A study of Mus musculus with 8 samples.

How the data were processed

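Single-nucleus RNA sequencing was performed on the hippocampus and the hypothalamus of adult C57BL/6J mice aged 8 to 14 weeks, with 10000 nuclei targeted per library. The 8 libraries were 1 per combination of tissue, light condition and time of day. The labels named 2 conditions, normal sleep cycle (NSC) and sleep cycle disturbance (SCD). The series text named a control with free sleep and rest-phase light, that is, light given during the hours in which mice rest, so SCD was read as rest-phase light because it was the only condition other than the control. The number of animals pooled per library, whether both tissues came from the same animals, the hour of sampling and the length of the light exposure were not given in the sources used here. The library names carried 6 by day and 18 by night with no unit. Whether these were hours of the clock or hours after lights on was not given, and the clock separation reads as another phase under each.

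Nuclei were isolated from frozen tissue with a nuclei isolation kit and barcoded in droplets with a 3′ kit. The deposited values were counts of unique molecular identifiers (UMIs) per gene and nucleus barcode, made by the authors with Cell Ranger 7.1.0 on genome build GRCm38, with no normalisation and with barcodes already filtered. Each library listed 32285 genes, and all deposited counts were whole numbers. Whether intronic reads were counted was not given in the sources used here. A 3′ count is not scaled by gene length, so no length correction was applied.

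Nuclei were kept at 500 or more detected genes and at most 5% mitochondrial UMIs. Scrublet in scanpy 1.11.5 (expected rate 0.06) was run per library, and its automatic threshold marked at most 0.13% of nuclei. Because this lay under 0.5%, the highest scores were removed at 0.8% per 1000 nuclei, a rule fixed in advance, which removed 6.36% to 15.59% per library. The 4 libraries of a tissue were clustered together on log-normalised counts with 3000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1 (igraph 0.11.9). Genes of the functional lists other than the myelin and homeostatic microglia lists were kept out of the clustering, as were mitochondrial and ribosomal protein genes. Clusters were named from 24 marker lists. The naming thresholds and a further clustering of hypothalamic neurons into GABAergic, glutamatergic and other neurons were set after the data were seen. Thalamic neurons were named in the clustering of the whole tissue and were not counted among the hypothalamic neurons. At resolution 2 the naming was revised after a first attempt left 0 dentate granule neurons named, and 3 attempts were made in all. Clusters that met no rule stayed unnamed.

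Counts were summed per class and library and expressed as CPM (counts per 1e6 counts of the class), with a pseudocount of 0.5 for log2 ratios. Within a tissue every comparison set 1 library against 1, with no replicates, so no test was run there and no p-value was computed. Sums carry exact Poisson 95% intervals, ratios exact conditional binomial 95% intervals, and shares exact binomial (Clopper-Pearson) 95% intervals. All of these cover counting error only and leave out differences between animals and preparations. Functional lists, 20 in number, were summarised by the median log2 ratio of members with at least 10 counts and by its percentile among 10000 random lists matched on mean expression in 20 bins. The genes of those random lists are not independent replicates, and a percentile is not a test. The pseudocount, the minimum of 10 counts and the 4 class shares printed were also chosen after the data were seen. Intervals of list medians came from 500 resamples of Poisson counts. The clock separation was the day minus night value of the median log2 ratio of REV-ERB and PAR-bZIP clock outputs minus that of genes controlled through the RORE element. It is positive where the outputs are higher by day, and its interval came from 2000 resamples.

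Across the 8 libraries, edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3 (TMM factors, filterByExpr) were run on class sums for astrocytes, oligodendrocytes and neurons. Night was compared with day with tissue and light as covariates, rest-phase light with control with tissue and time as covariates, and the interaction of light and time with all 3 terms. Tissue thus served as the replicate, and these tests address the average change over both tissues. A gene can pass through a change in a single tissue or library. For time and for light, a change that differs between the levels of the other factor also counts as error. If both tissues came from the same animals, the 8 libraries are not independent. Genes at a Benjamini-Hochberg adjusted p under 0.05 were counted, and lists were also counted with adjustment over the list alone.

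Genes named in the text followed a rule fixed before the data were examined, as were the gene lists, designs and the alternatives listed last. Any list member could be named. For light, the rule took the 3 genes highest and the 3 lowest in each of 4 classes per tissue and time, ranked by the bound nearest 1 of the interval of the ratio. For time it took 2 and 2. Candidates needed 100 counts and a CPM of at least 25% of the highest among other main neuron classes, astrocytes, oligodendrocytes, their precursors and microglia. This criterion was meant to keep out RNA from other cells, which it did not do in full. Avp, Pmch, Npy, Sst, Cck and Bc1 in glia, Sst and Fabp7 in hippocampal excitatory neurons, and Ttr met it. Ependymal and choroid plexus cells were not among the classes compared. Mitochondrial, ribosomal protein, sex-linked and haemoglobin genes and names of the Gm-number or Rik kind were not eligible in these rankings. For each 8-library test it took the 5 smallest p-values in each direction among genes past the threshold, with no such exclusion. Of the genes this rule took, 2 are not reported here. A ratio against a count of 0 was taken against a floor of 3 counts. Coordinates are GRCm38 from the GENCODE M21 annotation.

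The methods were tested on simulated data. For the ratio intervals, Poisson counts were drawn around the pooled proportions of a light and a control day library, with 2-fold changes put in. The intervals held the true ratio for 95.5% to 96.0% of genes. Such draws hold counting error only, so this checks the calculation and not the variation between real libraries. The 8-library tests recovered 53% to 79% of 2-fold changes for time and for light, and 7% to 54% for the interaction. False genes among calls stayed at or under 7.45% except for the interaction in neurons, at 13.84%. For these tests each simulated library was drawn independently around a common mean, with no tissue effect and no structure shared between libraries. The rates therefore do not cover errors from such structure in the real libraries.

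Alternatives fixed in advance were nuclei with 1000 or more genes, doublets kept, Leiden resolution 2, TMM factors in place of CPM, totals without mitochondrial genes and Malat1, each nucleus weighted equally, DESeq2 1.42.0 Wald tests, DESeq2 size factors in edgeR, no filter on low counts, and leaving out each library in turn. A fit without both rest-phase light night libraries and a fit with the mitochondrial share of the class as a covariate were added after the data were seen. Counts were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Reads were not used here, and no correction for RNA from broken cells was applied.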

Results

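The data were UMI counts from 8 single-nucleus RNA libraries, 4 from the hippocampus and 4 from the hypothalamus of mice kept under control conditions or under rest-phase light and sampled by day or by night. Each group held 1 library, so there were no replicates. In the hippocampus the totals were 40151851 UMIs for control day, 46355179 for control night, 46614300 for light day and 40445731 for light night. In the hypothalamus they were 36530785, 59958911, 36348679 and 55670317 in the same order. After filtering, 7446, 7995, 8131 and 9859 hippocampal nuclei and 9533, 16447, 10054 and 10729 hypothalamic nuclei remained. Mitochondrial genes took 6.94%, 3.46%, 4.34% and 2.02% of UMIs in the hippocampal libraries and 2.28%, 2.43%, 2.19% and 1.02% in the hypothalamic ones, so that the rest-phase light night library was the lowest in each tissue. The limit of 5% mitochondrial UMIs removed 12082 of 20074 barcodes from the hippocampal control day library and 737 of 12787 from the hypothalamic light night library. Xist, which is expressed from the inactive X chromosome of females, lay between 1.31 and 1.86 CPM in the hippocampal and between 0.192 and 0.550 CPM in the hypothalamic libraries, and the Y-linked Uty between 118 and 234 CPM over all 8.

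The hippocampal libraries differed in cell makeup. Neurons made up 84.8% of kept nuclei (95% interval 83.9 to 85.6) in the control day library, 71.9% (70.9 to 72.8) in control night, 84.1% (83.3 to 84.9) in light day and 80.0% (79.2 to 80.8) in light night. Oligodendrocytes, the myelinating cells, made up 1.52%, 9.91%, 4.01% and 7.76% in the same order, and astrocytes 2.001%, 5.89%, 3.85% and 2.87%. Glia held fewer UMIs per nucleus than neurons, with medians of 1068 in oligodendrocytes and 2710.5 in neurons of the control day library, so depth and the mitochondrial limit both bear on these shares. In the hypothalamus the neuron share ranged from 55.6% to 57.3% and the astrocyte share from 10.5% to 12.6%. The subclusters within the neurons varied between libraries. The largest, outside both transmitter classes, held 502, 1417, 715 and 317 nuclei in control day, control night, light day and light night. GABAergic subclusters with 292, 259 and 356 nuclei in control night held 30, 64 and 482 in light night. Values of all hypothalamic neurons thus also compare different mixtures. Oligodendrocytes there ranged from 12.4% in light day to 16.6% in light night. Thalamic neurons, which lie outside the hypothalamus, numbered 368, 1065, 151 and 690, a measure of how the dissections differed. Unnamed nuclei made up 8.69%, 6.04%, 4.17% and 4.62% of the hippocampal libraries and 7.37%, 5.98%, 10.99% and 3.53% of the hypothalamic ones. Hypothalamic astrocytes formed 2 large clusters, which held 597 and 600 nuclei of control day, 650 and 1084 of control night, 451 and 778 of light day, and 1128 and 118 of light night.

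The first comparison addressed the question in the title of the series, whether rest-phase light changes the hippocampal clock. In hippocampal neurons the REV-ERB and PAR-bZIP clock outputs were lower by day than by night in the controls and higher by day than by night under rest-phase light. Dbp, a PAR-bZIP transcription factor and direct target of the clock, was at 11.2 CPM (95% interval 9.71 to 12.7) by day and 13.9 (12.5 to 15.3) by night in the controls, against 14.3 (12.9 to 15.7) and 7.25 (6.29 to 8.31) under light. Nr1d1, which encodes REV-ERBα, was at 5.16 and 5.31 CPM in the controls and at 6.32 (5.45 to 7.30) and 3.96 (3.26 to 4.76) under light. Arntl, which encodes BMAL1, ran the other way under light, at 39.2 (36.9 to 41.5) by day and 44.3 (41.9 to 46.8) by night, and was at 41.0 and 39.4 in the controls. The clock separation was -0.37 (-0.49 to -0.18) in control neurons and 0.41 (0.25 to 0.53) in neurons under rest-phase light, a difference of 0.78 (0.51 to 0.93) on the log2 scale.

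The same order of values held in the neuron classes. CA pyramidal neurons gave -0.32 (-0.58 to -0.11) in the controls and 0.51 (0.22 to 0.84) under light, and dentate granule neurons -0.11 (-0.35 to 0.05) and 0.37 (0.18 to 0.48), the latter 0.13 at resolution 2. In the hypothalamus, which holds the central clock, all neurons gave -0.15 (-0.22 to 0.14) and 0.39 (0.19 to 0.55), GABAergic neurons -0.02 and 0.42, and glutamatergic neurons -0.22 and 0.32. The hypothalamic difference between light and control was 0.54 (0.16 to 0.65). Dbp in hypothalamic neurons was at 13.1 and 14.8 CPM by day and night in the controls, and at 15.02 and 8.40 under light. Separations in astrocytes and oligodendrocytes were not distinguishable from 0 at this depth in either tissue, as their intervals reached or included 0. In the hippocampus, Per1 and Per2, core repressors of the clock, were at 10.6 and 20.3 CPM in control night neurons and at 7.60 and 10.96 in light night neurons.

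**Figure D1:**
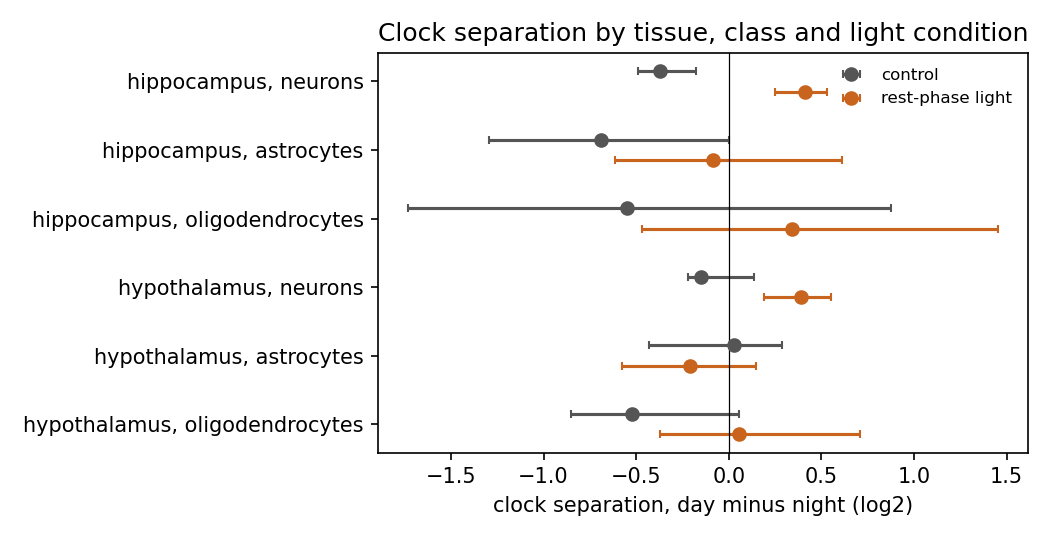
Clock separation (log2, day minus night of outputs against RORE-controlled genes) by tissue, class and light condition, with 95% counting intervals as bars and 1 pair of libraries per point. In hippocampal neurons the control lay at -0.37 and rest-phase light at 0.41.

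Short transcripts were lower at night than by day under rest-phase light as a whole, which stands beside these clock values because the outputs include short genes. In hippocampal neurons the median night to day log2 ratio under light ran from -0.72 among the shortest eighth of genes to 0.18 among the longest, and in the controls from -0.23 to 0.04. Among 10000 random pairs of lists matched to the clock lists on gene length and expression, the light separation of 0.41 lay at percentile 68.92, with a random median of 0.31. The control separation of -0.37 lay at percentile 0.55. With 1 library per group neither separation was tested against differences between animals.

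The comparison of rest-phase light with control by day asked what the light changed in the phase in which it was given. In the hypothalamus by day, neuropeptide and activity-linked transcripts were higher under light. Avp, which encodes vasopressin, had a ratio of 2.14 (1.89 to 2.44) in GABAergic neurons, and Fos, an immediate early gene, 2.55 (1.75 to 3.78) in glutamatergic neurons. Npvf, which encodes RFamide peptides, had a ratio of 2.22 (1.47 to 3.39), and Csta2 of 2.49 (1.64 to 3.87). The subcluster with Csta2 among its markers held 54 nuclei in control day and 81 in light day, and that with Npvf 45 and 44. Avp led the markers of a glutamatergic subcluster with 21 and 20, so its GABAergic value may also read RNA from other cells. A GABAergic subcluster marked by Vipr2 held 3 and 31, so cell makeup differed within that class. The median over the neuropeptide list in hypothalamic neurons was 0.30 (0.25 to 0.38) on the log2 scale and over the immediate early gene list 0.36 (0.09 to 0.48), the latter at percentile 99.98 among random lists. Hypothalamic GABAergic neurons had lower Hmcn1 (0.554), Crb1 (0.556) and Ano1 (0.559), and glutamatergic neurons lower Wnt4 (0.510), Myo5b (0.634) and Nxpe4 (0.667). Subclusters with Ano1 and Myo5b among their markers held 108 and 244 nuclei in control day and 71 and 182 in light day. Of the 3 with Hmcn1, the GABAergic subcluster held 127 nuclei in control day and 76 in light day. The subcluster outside both transmitter classes held 118 and 176, and the glutamatergic subcluster 45 and 44. In astrocytes, Ahdc1 (0.498) and Cck (0.482), a neuropeptide of neurons, were lower. Avp was also higher in astrocytes (2.07) and oligodendrocytes (1.62), cell types that do not make vasopressin.

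In the hippocampus by day, Xlr4b, an X-linked gene that is expressed in the brain, was higher under light in dentate granule neurons with a ratio of 7.02 (3.70 to 14.97). Plxna4os2, a non-coding transcript, had a ratio of 2.36 (2.03 to 2.76) there, and AY036118 was higher by 1.79 to 1.94 in dentate granule neurons, astrocytes and oligodendrocytes. CA pyramidal neurons had higher Il12rb2 (2.37), CT009536.1 (2.26) and Wdsub1 (1.90). Lower transcripts were Cryab (0.558) and Aldoc (0.654) in dentate granule neurons, Prr16 (0.501) and Adamtsl1 (0.596) in CA pyramidal neurons, and Pcdh7 (0.330), Nckap5 (0.393) and Xkr4 (0.471) in oligodendrocytes. Against the same control day oligodendrocytes, Pcdh7 was also lower in control night, with a ratio of 0.380 (0.298 to 0.488). Dcn, a proteoglycan, was at 0.281 in dentate granule and 0.531 in CA pyramidal neurons. Against the same control day dentate granule neurons, Dcn was also lower in control night, with a ratio of 0.091 (0.056 to 0.142). For the CA pyramidal value, a CA1 cluster with Dcn among its markers held 482 nuclei in control day and 286 in light day. The immediate early gene median in hippocampal neurons was 0.27 (0.18 to 0.37).

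At night the comparison asked what the exposure left in the active phase. In the hypothalamus, neuropeptide transcripts were lower under light. Npy, an appetite-promoting peptide, had a ratio of 0.233 (0.178 to 0.301) and Oxt, which encodes oxytocin, 0.344 (0.321 to 0.369) in GABAergic neurons. Tac2 was at 0.259 (0.198 to 0.335) and Cartpt at 0.281 (0.230 to 0.341) in glutamatergic neurons. Pmch, which encodes melanin-concentrating hormone, was at 0.360 and 0.336 in the same classes. Oxt marked a glutamatergic subcluster, and Pmch a subcluster outside both classes, so these values also read RNA from other cells. Tac2 was among the markers of a GABAergic subcluster with 198 nuclei in control night and 176 in light night. The value of Tac2 may thus read RNA from other cells too. Npy stood at 38.9 CPM in control night oligodendrocytes and at 22.3 in GABAergic neurons, and its ratio in oligodendrocytes was 0.165. Its GABAergic value may therefore also read RNA from other cells. The neuropeptide median was -1.09 (-1.17 to -0.96) in neurons, and it was -1.39 in astrocytes and -1.32 in oligodendrocytes. Pmch stood at 352 CPM (329 to 376) in hypothalamic light night oligodendrocytes and at 881 (843 to 920) in the control ones, in a cell type that does not make it. Immediate early genes were lower in neurons of both tissues, with medians of -0.58 (-0.77 to -0.46) in the hippocampus and -0.65 (-0.85 to -0.51) in the hypothalamus. In hypothalamic neurons the monoamine and histamine synthesis list was higher, with a median of 0.65 (0.50 to 0.93). A neuron subcluster marked by Slc6a3, Ddc and Th held 108 nuclei in light night and 21 in control night.

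Glia of the hypothalamus at night had higher Acss2, which makes acetyl-CoA from acetate, with a ratio of 2.08 (1.82 to 2.39) in astrocytes, and higher Gss, which makes glutathione, with 2.34 (1.78 to 3.09). Oligodendrocytes had higher Tmem132d (2.69) and Slc7a15 (2.22). Ptgds, which makes prostaglandin D2, a sleep-promoting lipid, was at 0.3002 (0.268 to 0.335) in astrocytes, and Cst3 at 0.342 in oligodendrocytes. The large hypothalamic astrocyte clusters given above differed in proportion between these night libraries, so the astrocyte values also compare different mixtures. In hippocampal neurons at night higher transcripts beside Ttr were Cfap299 (2.51 in dentate granule and 2.46 in CA pyramidal neurons), Trhr (2.42), Dpyd (1.89) and Luzp2 (1.84). Cfap299 is also on the ependymal marker list. The criterion for candidates did not compare ependymal cells, so RNA from them was not excluded. Lower ones included Shoc1 (0.186) and Col11a1 (0.336) in CA pyramidal neurons, Lrrc45 (0.384) and Prpf4b (0.463) in dentate granule neurons, and the chaperone Hsp90ab1 (0.509) and Kif5b (0.417) in astrocytes. Wfs1 was at 0.236 in CA pyramidal neurons and marks CA1, whose share of those neurons also differed between the libraries. A CA1 cluster with Col11a1 among its markers at resolution 2 held 304 nuclei in control night and 21 in light night, and a dentate granule cluster with Trhr among its markers 489 and 1318. Pgam1 (0.436) and Dynll2 (0.442) were lower in oligodendrocytes. The glucocorticoid-responsive median was -0.64 (-0.77 to -0.38) in hippocampal neurons and -0.55 (-0.78 to -0.28) in hippocampal oligodendrocytes, and cholesterol synthesis was higher in hippocampal astrocytes at 0.45 (0.20 to 0.64).

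Ttr, which encodes transthyretin and is made by the choroid plexus, was higher in the hippocampal light night library with ratios of 95.4 (54.4 to 185) in dentate granule neurons, 236 (41.3 to 9398) in astrocytes and 116 (39.2 to 567) in oligodendrocytes. The astrocyte value rested on 1 control count and the oligodendrocyte value on 3.

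Oxidative phosphorylation and ribosomal protein transcripts were lower in the rest-phase light night libraries in the 3 classes compared. Medians of nuclear oxidative phosphorylation genes against control night were -0.39 in neurons, -0.48 in astrocytes and -0.30 in oligodendrocytes of the hippocampus, and -0.95, -0.99 and -0.95 in the hypothalamus. Ribosomal protein medians were -0.51, -0.39 and -0.31 and then -1.16, -1.10 and -0.99. Haemoglobin transcripts, from blood, were lower in neurons by -1.68 in the hippocampus and -2.11 in the hypothalamus. These shifts accompany the lower mitochondrial share of the same libraries before filtering, but not in each class. The log2 ratio of summed mitochondrial counts was -0.15, -0.02 and 0.06 in hippocampal neurons, astrocytes and oligodendrocytes. In the hypothalamus it was -0.89, -0.65 and -0.47. Neuropeptide, immediate early and chaperone transcripts have to be read beside the shifts in oxidative phosphorylation and ribosomal protein transcripts. TMM scaling moved the median of all genes by 0.14 in hippocampal neurons and 0.11 in hypothalamic oligodendrocytes for this comparison.

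**Figure D2:**
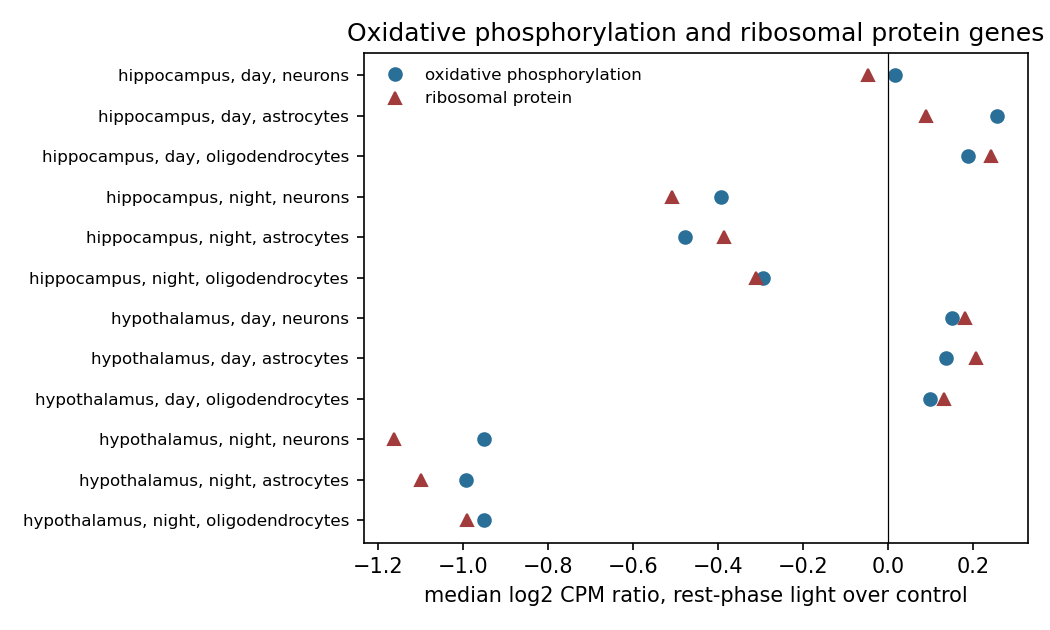
Median log2 ratio (rest-phase light over control) of nuclear oxidative phosphorylation genes and ribosomal protein genes, by tissue, time of day and class. At night all 6 combinations of tissue and class lay below 0, from -0.30 to -1.16.

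Across the 8 libraries the light comparison asked for effects averaged over both tissues and both times. In astrocytes 1 gene of 12090 tested rose, Ttr, by 5.06 on the log2 scale (adjusted p = 0.00351 by edgeR), with 532 genes at an unadjusted p under 0.05. In oligodendrocytes 0 of 11471 and in neurons 0 of 19855 genes passed by edgeR, with 668 and 1825 at an unadjusted p under 0.05. DESeq2 gave 0, 0 and 2 genes. Ttr stood at 9.86, 1.21, 5.68 and 285 CPM in hippocampal astrocytes (control day, control night, light day, light night) and at 0.582, 0.491, 0.631 and 0.466 in hypothalamic ones, so the call came from the hippocampal light night library. Without hippocampal light day Ttr still passed, at 5.82, and 0 genes passed without any other single library. Without hippocampal control night Ttr was at 0.06 (adjusted p = 0.999). Adjusted over the list alone, 6 heat shock and unfolded protein response genes and 2 myelin genes fell in astrocytes, 2 heat shock genes fell in oligodendrocytes, and in neurons 4 monoamine genes rose while 4 haemoglobin and 2 myelin genes fell. No member of the clock output, RORE-controlled, immediate early, synapse, glucocorticoid, cold-inducible, neuropeptide, microglia, cholesterol or adenosine, orexin and melatonin lists passed in the 3 classes over the list alone, and in the other clock gene list 1 gene fell in astrocytes.

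The comparison of night with day asked which transcripts follow the time of day on average over both tissues. Of 12 measured glucocorticoid-responsive genes, 3 rose at night in astrocytes and 3 in oligodendrocytes. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.02 in astrocytes (adjusted p = 4.4e-05) and by 1.28 in oligodendrocytes (0.00201), higher at night in 4 of 4 pairs of libraries. In hypothalamic control astrocytes it was at 12.8 CPM (8.02 to 19.4) by day and 71.7 (60.5 to 84.3) by night, and under light at 14.5 (9.20 to 21.8) and 52.2 (43.0 to 62.8). Zbtb16, a zinc finger factor, rose by 1.15 in astrocytes and 1.01 in oligodendrocytes. Sgk1, a kinase induced by glucocorticoids, rose by 1.18 in oligodendrocytes and Tsc22d3, which encodes GILZ, by 0.86 in astrocytes. Of the 12, 7 had a log2 fold change above 0 in astrocytes and 10 in oligodendrocytes. Adjusted over the list alone, 5 rose and 2 fell in astrocytes and 7 rose and 1 fell in oligodendrocytes.

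**Figure D3:**
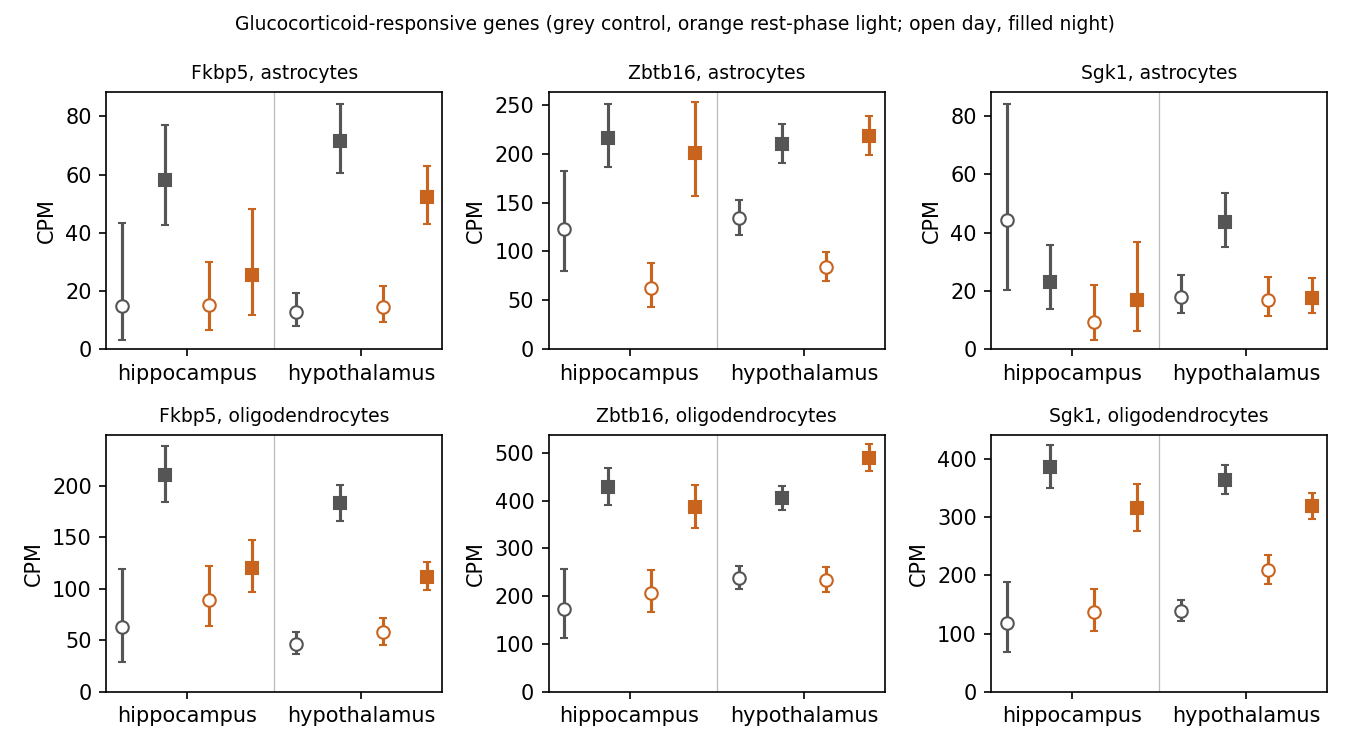
Fkbp5, Zbtb16 and Sgk1 in astrocytes and oligodendrocytes of each library (CPM, 95% Poisson intervals as bars). Fkbp5 was higher at night than by day in each of the 4 pairs of libraries in both classes, for example 12.8 and 71.7 CPM in hypothalamic control astrocytes.

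Other genes changed with time in astrocytes, where 106 rose and 183 fell. Proportions of the large hypothalamic astrocyte clusters also differed between day and night libraries, so the makeup of the class can bear on these genes. Those that rose included Zfhx3, a transcription factor of the central clock (1.42), Slc24a4 (2.08) and Megf9 (1.33), together with Per2 (0.84), Rora (0.80), Lss (1.15) and Hmgcs1 (0.61). Those that fell included Fabp7, a brain lipid-binding protein (-1.33), Cbr3 (-1.83), Gm19951 (-1.30), Chchd2 (-1.10) and Hint1 (-1.0005). In oligodendrocytes 94 rose and 223 fell. Adipor2, an adiponectin receptor (1.10), Zfand4 (1.43) and Bcl2l1, which protects from apoptosis (1.05), rose, while Ndufab1 (-1.07), Chchd2 (-1.03), Atp5o (-1.003), Rps6 (-0.96), Snhg9 (-1.54) and the myelin gene Opalin (-0.66) fell. In neurons 1142 rose and 1427 fell. The rise included 1700015H07Rik (0.74), Gm10308 (1.49), Gm36988 (0.82), Pkd2l2 (0.57) and Nlk (0.62), and the fall Gm20110 (-2.80), Gm47578 (-1.70), Xlr4b (-4.78), Atp5o (-0.97) and Rps6 (-0.93). Neurons also shared the rise of Zbtb16 (0.66), Fkbp5 (0.53), Sgk1 (0.39) and Klf9 (0.33), the 4 of 15 glucocorticoid-responsive genes that passed, while 6 of the 15 had a log2 fold change above 0, with a median of -0.20. Nr1d2 (0.30) and Homer1 (0.46) rose there, and Jun (-0.56), Pomc (-1.09), Sst (-0.95) and Tac1 (-0.84) fell.

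Groups of genes fell together at night. Of 21 oxidative phosphorylation genes, 7 fell in astrocytes, 7 in oligodendrocytes and 16 in neurons, and 15, 14 and 18 adjusted over the list alone. Of the 4 haemoglobin genes, 2, 1 and 4 fell. Of the heat shock list 0 of 15, 1 of 14 and 9 of 18 fell, and 6, 7 and 13 adjusted over the list alone, among them Hsp90aa1 and Hspa8 (-0.61 in neurons). Ribosomal protein genes were lower at night as well, with night over day medians of -0.75 in hippocampal control neurons, -1.23 in hippocampal and -1.52 in hypothalamic light neurons, and -0.17 in hypothalamic control neurons. In hypothalamic control glia they were -0.06 in astrocytes and -0.14 in oligodendrocytes. Oxidative phosphorylation medians of the hypothalamic control pair were small too, at -0.15 in neurons, -0.04 in astrocytes and -0.09 in oligodendrocytes. Cholesterol synthesis had 2 of 15 genes up in astrocytes and 6 adjusted over the list alone. Of the myelin list 0 of 11, 1 of 12 and 0 of 12 fell, and 0, 2 and 0 adjusted over the list alone. Of 7 clock outputs 0, 0 and 1 passed, and of 10 other clock genes 2, 0 and 0. Adjusted over the list alone 3 outputs rose and 1 fell in astrocytes and 2 rose in neurons. Among RORE-controlled genes 0 passed in each class, and adjusted over the list alone 1 rose in astrocytes, 1 in oligodendrocytes, and 2 rose and 1 fell in neurons. In neurons the synapse list had 2 of 23 genes up, Camk4 (0.40) and Shank2 (0.29), the immediate early list 1 up and 1 down of 23, the neuropeptide list 3 down of 23 and the homeostatic microglia list 1 down of 9. Reactive astrocyte, activated microglia, cold-inducible, monoamine, and adenosine, orexin and melatonin lists had 0 members past the threshold in the 3 classes by edgeR; adjusted over the list alone, 2 cold-inducible genes fell in neurons. The choroid plexus list had Ttr up in astrocytes, with its counts in the hippocampal light night library as given for light, and the sex-linked list had Uty (0.38) and Ddx3y (0.28) up in neurons.

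At an unadjusted p under 0.05 the night comparison had 2106, 1981 and 6236 genes in astrocytes, oligodendrocytes and neurons, and DESeq2 called 288, 346 and 3454. The counts fell without any single light library, of day as well as night, and they also moved without control libraries. Without both light night libraries 3, 5 and 1 genes remained past the threshold, among them Fkbp5 in both glial classes, and with the mitochondrial share as a covariate 10, 10 and 0. In astrocytes 82 genes passed without hippocampal control night, 15 without hippocampal light day, 15 without hippocampal light night, 711 without hypothalamic control day, 1254 without hypothalamic control night, 5 without hypothalamic light day and 5 without hypothalamic light night. In oligodendrocytes the counts were 65, 20, 23, 561, 1321, 6 and 20 in that order. In neurons 0 passed without hippocampal light day, 1 without hippocampal light night, 3888 without hypothalamic control night, 1 without hypothalamic light day and 670 without hypothalamic light night. Fkbp5 passed in both glial classes in each of these edgeR fits.

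Within single tissues the glucocorticoid list was given for each light condition. The night over day median in oligodendrocytes was 1.20 (0.82 to 1.81) in the hippocampus and 0.77 (0.54 to 0.89) in the hypothalamus under control conditions, and 0.28 (-0.06 to 0.65) and 0.20 (-0.04 to 0.57) under light, and the hypothalamic intervals overlap. The oligodendrocytes of hippocampal control day held only 143678 UMIs. Ribosomal protein medians of the same oligodendrocyte pairs were -0.43 and -0.14 in the controls and -0.99 and -1.31 under light. The contrast between light and control has to be read beside these shifts. In astrocytes the glucocorticoid median was 0.78 and 0.63 in the controls and 0.62 and 0.05 under light. The interaction took 0 of 12 of these genes past the threshold in either glial class by edgeR, and over the list alone 2 lower in oligodendrocytes and 1 higher in astrocytes. In control pairs the rule named Sgk1 with ratios of 3.26 (2.01 to 5.65) and 2.63 (2.27 to 3.06), and Zfand4 with 3.37 (2.45 to 4.71) in the hypothalamus. Megf9 (2.16) and Cdk5r1 (2.29) were higher at night in hypothalamic control astrocytes, Hif3a (3.08) and Asic2 (2.52) in hippocampal ones, Chdh (2.46) and Npy (2.21) in hypothalamic GABAergic neurons, and Zbtb18 (2.85) and Actb (1.77) in glutamatergic neurons. Npy stood higher in control night oligodendrocytes (38.9 CPM) than in GABAergic neurons (22.3), so its value may read RNA from other cells. The large hypothalamic astrocyte clusters differed in proportion between the control libraries, which can bear on Megf9 and Cdk5r1. Olfm4 (2.72) was higher in dentate granule neurons and Cbfa2t3 (2.26) in CA pyramidal neurons. Sass6 had a ratio of 15.04 (2.65 to 599) in hippocampal control oligodendrocytes on 1 day count. Lower at night in the controls were Cmss1 (0.486, 0.469 and 0.430 in GABAergic neurons, glutamatergic neurons and oligodendrocytes of the hypothalamus), Sst (0.260) in dentate granule and Fabp7 (0.209) in CA pyramidal neurons, which are transcripts of interneurons and glia.

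Under rest-phase light, Megf9 (3.00) and Zbtb16 (2.61) were higher at night in hypothalamic astrocytes, Adipor2 (2.20) in oligodendrocytes, Agtr1a (2.84) in glutamatergic neurons and Vipr2, the receptor for vasoactive intestinal peptide (2.70), in GABAergic neurons. The subcluster marked by Agtr1a held 45 nuclei by day and 94 by night, and that marked by Vipr2 held 31 and 61. Lower were Fos (0.142) in glutamatergic neurons and Bc1, a cytoplasmic non-coding RNA of neurites, in GABAergic (0.257) and glutamatergic (0.248) neurons of the hypothalamus and in CA pyramidal neurons (0.178). Ndufa13 was at 0.277 in GABAergic neurons and Tmsb10 at 0.257 in astrocytes. The large hypothalamic astrocyte clusters given above differed in proportion between these day and night libraries. The hypothalamic astrocyte values of Megf9, Zbtb16 and Tmsb10 thus also compare different mixtures. Xlr4b had 0 counts at night in dentate granule neurons and 135 by day. Zbtb16 had a ratio of 3.21 in hippocampal astrocytes, and Chchd2 of 0.247. TMM scaling moved the median of all genes by 0.14 in hippocampal control oligodendrocytes, and under light by 0.23 in hippocampal and 0.19 in hypothalamic neurons.

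The interaction asked whether the day to night change differed between light and control on average over both tissues. In astrocytes 39 genes had a higher and 102 a lower night to day change under light. Acss2 (1.46, adjusted p = 0.0100 by edgeR), Kirrel3, an adhesion protein (0.95), A330076C08Rik (1.76), Npas3 (0.78) and 9630014M24Rik (1.45) were higher. Cox8a (-1.30, 0.00894), Tmsb10 (-1.91), Ndufa13 (-1.74) and Oxt (-1.90) were lower. The proportions of the large hypothalamic astrocyte clusters also differed between the libraries, so the makeup of the class can bear on these genes. Of the neuropeptide list 7 of 17 genes were lower and 11 adjusted over the list alone, among them Avp (-1.72), Pmch (-1.45) and Hcrt (-1.47), and 3 of 21 oxidative phosphorylation genes were lower and 13 adjusted over the list alone. Astrocytes do not make these peptides. None of Oxt, Avp, Pmch and Hcrt passed without any 1 of the 4 hypothalamic libraries, and without hypothalamic control day, control night, light day and light night Oxt was at -5.99, -1.71, 3.11 and 1.47, Pmch at -4.81, -5.76, 2.86 and -4.02 and Hcrt at -4.25, 1.74, 2.06 and 4.57. By DESeq2 Hcrt was at 0.49. In oligodendrocytes 0 genes passed by edgeR and 15 by DESeq2, and in neurons 1 passed by edgeR, 1700007F19Rik (-1.89, adjusted p = 0.0444), and 1176 by DESeq2. No clock output or RORE-controlled gene passed in neurons by edgeR. A CA1 cluster marked by 1700007F19Rik at resolution 2 held 200, 304, 310 and 21 nuclei in hippocampal control day, control night, light day and light night. At an unadjusted p under 0.05 there were 1681, 1467 and 4061 genes. Adjusted over the list alone, 12 oxidative phosphorylation and 10 neuropeptide genes were lower in oligodendrocytes, and in neurons 10 oxidative phosphorylation, 8 immediate early, 6 neuropeptide, 4 heat shock, 4 glucocorticoid-responsive and 4 haemoglobin genes were lower and 5 synapse genes higher. DESeq2 gave 0 genes in astrocytes, where the count was 236, 689, 41, 60, 54, 96 and 33 without hippocampal control day, control night, light day and light night and hypothalamic control day, control night and light day, and 0 without hypothalamic light night. In oligodendrocytes it was 18, 672, 0, 113, 32, 29, 0 and 1 in the order just given, with hypothalamic light night last, and in neurons 0, 1423, 0, 0, 4, 927, 0 and 1.

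In GRCm38 coordinates, Fkbp5 (ENSMUSG00000024222) lies on chromosome 17 from 28399094 to 28517527, Sgk1 (ENSMUSG00000019970) on chromosome 10 from 21882184 to 21999903, Zbtb16 (ENSMUSG00000066687) on chromosome 9 from 48654297 to 48836222 and Zfhx3 (ENSMUSG00000038872) on chromosome 8 from 107942644 to 108961630. Dbp (ENSMUSG00000059824) lies on chromosome 7 from 45705088 to 45710203, Arntl (ENSMUSG00000055116) on chromosome 7 from 113207465 to 113314126, Nr1d1 (ENSMUSG00000020889) on chromosome 11 from 98767932 to 98775333 and Ttr (ENSMUSG00000061808) on chromosome 18 from 20665280 to 20674321. All are protein-coding genes, and counts are given per gene.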

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

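The tests of the control separation, of the light separation in hippocampal neurons, of the hypothalamic difference and of Ttr were chosen only after the results were seen, while the other predictions were written before their results, that of the clock difference after the separations had been seen. The following results were marked by rules fixed in advance because the 2 light conditions differed in their change between day and night.

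In astrocytes the interaction of light and time took Acss2 (1.46), Kirrel3 (0.95), A330076C08Rik (1.76), Npas3 (0.78) and 9630014M24Rik (1.45) upward and Cox8a (-1.30), Tmsb10 (-1.91), Ndufa13 (-1.74) and Oxt (-1.90) downward. Oxt was at 3.11 without hypothalamic light day and 1.47 without hypothalamic light night. In neurons it took 1700007F19Rik downward (-1.89), which marked a CA1 cluster at resolution 2 with 304 nuclei in control night and 21 in light night. The clock separation took opposite signs under control and light, with a difference of 0.78 in hippocampal neurons and 0.83 in CA pyramidal neurons. Neither difference was tested within the hippocampus because each group held 1 library. The interaction test in neurons over both tissues took no clock output or RORE-controlled gene past the threshold by edgeR.

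The clock separation in hippocampal neurons could reflect a changed phase of the neuronal clock or a loss of short transcripts from the light night library. The light separation of 0.41 lay at percentile 68.92 (39.77 to 84.44 over its counting interval) among random lists matched on gene length and expression, and the hypothalamic difference of 0.54 at percentile 87.21 (31.3 to 94.33), so a loss of short transcripts alone can account for both. For the hippocampal difference, at percentile 98.77 (88.58 to 99.76), the 2 explanations cannot be told apart. The same holds for the control separation below 0, at percentile 0.55 (0.07 to 5.57), against a shift of short against long transcripts between the 2 control libraries. These percentiles were read at both ends of the counting interval, a rule that replaced the percentile of the value alone after the results were seen, and by the value alone the loss of short transcripts would have been excluded for the hippocampal difference, and the shift of short against long transcripts for the control separation.

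The lower oxidative phosphorylation genes in the light night libraries could come from less cytoplasmic RNA among the nuclei or from a lower mitochondrial content of the cells. Ribosomal protein genes, which are cytoplasmic too, were lower in 6 of 6 combinations of tissue and class, as the first explanation requires. Both groups are also short genes, so this does not set less cytoplasmic RNA apart from the loss of short transcripts weighed for the clock. In 0 of 6 did oxidative phosphorylation fall further than ribosomal protein genes by the bound set, which excludes the second as the only cause. Cox8a and Ndufa13 encode subunits of the respiratory chain, and less cytoplasmic or short RNA is a candidate explanation for the genes with a lower change in the astrocyte interaction.

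Every other division of the 8 libraries into 4 and 4 that could be fitted was tested in the same way. For night against day the real division was reached, itself included, in 2 of 33 divisions in astrocytes (289 genes, highest other 590) and 2 of 33 in oligodendrocytes (317 and 739), so chance was not excluded for the glial night counts, and in 1 of 33, itself, in neurons (2569, highest other 1). For light against control it was 23 of 33 in astrocytes (1 gene, highest other 421), 33 of 33 in oligodendrocytes (0 and 384) and 33 of 33 in neurons (0 and 292). For the interaction it was 1 of 32, itself, in astrocytes (141, highest other 139), 32 of 32 in oligodendrocytes (0 and 169) and 6 of 32 in neurons (1 and 113). Every division reaches a count of 0, so those 3 shares decide nothing. The division with 590 and 739 genes set both hippocampal control libraries and both light night libraries against the rest, which points to a structure of the samples other than time of day.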

How the results depend on the processing

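The fits without both light night libraries and with the mitochondrial share were chosen only after the results were seen. TMM factors and totals without mitochondrial genes and Malat1 cancel in the clock separation by construction. Of 20 clock separations 20 kept their call with doublets kept and with each nucleus weighted equally. Of 160 named genes, 2 turned direction at 1000 or more genes and 0 under each other alternative, while 26 moved at 1000 or more genes, 11 under TMM factors, 8 at resolution 2, 2 with each nucleus weighted equally and 1 with doublets kept. Of 447 list medians 81 moved at 1000 or more genes, 61 under TMM factors, 13 with each nucleus weighted equally, 5 without mitochondrial genes and Malat1 and 1 with doublets kept. The cause was not tested for any of the moves given here. No paired analysis was possible because the labels pair no animals. A fit blocked on the 4 combinations of tissue and light could have been made and was not run.

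At 1000 or more genes, neurons made up 88.4%, 83.7%, 90.8% and 92.2% of the hippocampal libraries (control day, control night, light day, light night) and 75%, 74.2%, 78.5% and 68.2% of the hypothalamic ones. Astrocytes made up 0.636%, 4.15%, 2.36% and 0.590%, then 6.50%, 3.21%, 4.80% and 9.06%, and oligodendrocytes 0.295%, 2.93%, 1.06% and 0.367%, then 2.74%, 1.81%, 1.91% and 5.78%. Unnamed nuclei were at 5.09% in hippocampal control night, 3.49% in light day, and 5.84%, 7.65% and 8.73% in hypothalamic control day, control night and light day. The light astrocyte clock separation of the hypothalamus moved to -0.72. Slc7a15 in hippocampal light oligodendrocytes turned to -0.19 and Lsm1 in hypothalamic day oligodendrocytes to -0.16. In oligodendrocytes the synapse list turned to 0.35 in the hippocampus at night and 0.35 in the hypothalamus by day, and under control conditions the hypothalamic immediate early, activated microglia and neuropeptide lists turned to -0.056, -0.056 and -0.064. Test counts were 17 for time in oligodendrocytes, 0 for light in astrocytes, 29 for the interaction in astrocytes and 418 in neurons.

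With doublets kept, neurons were at 70.1%, 82.5% and 78.2% in hippocampal control night, light day and light night and 54.3%, 56.1%, 55.5% and 53.1% in the hypothalamus. Astrocytes were at 11.8%, 9.11% and 10.7% in hypothalamic control day, control night and light night, and oligodendrocytes at 13.4%, 11.6% and 15.2% there and 7.17% in hippocampal light night. Unnamed nuclei were at 8.48%, 5.98% and 6.88% in hippocampal control night, light day and light night and 10.97%, 10.9%, 14.1% and 8.43% in the hypothalamus. The interaction gave 12 genes in oligodendrocytes and 0 in neurons. At resolution 2, neurons were at 85.9% and 73.1% in hippocampal control day and night, unnamed nuclei at 7.56%, 4.80% and 3.37% in control day, control night and light day, the dentate light separation at 0.13, and the interaction gave 12 genes in oligodendrocytes and 180 in neurons.

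DESeq2 gave 0 genes for light in astrocytes and 2 in neurons, and for the interaction 0, 15 and 1176 in astrocytes, oligodendrocytes and neurons, with Hcrt in astrocytes turning to 0.49. Its size factors in edgeR gave 88, 11 and 634 for the interaction. Without the filter on low counts, time gave 457 genes in astrocytes and 502 in oligodendrocytes, light 1 in oligodendrocytes and 2 in neurons, and the interaction 106 in oligodendrocytes and 994 in neurons. Without both light night libraries, time gave 3, 5 and 1 genes and light 0 in astrocytes. With the mitochondrial share as a covariate, time gave 10, 10 and 0, and in neurons Atp5e turned to 0.13 and Sst to 0.15.

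Leaving out 1 library, time counts ranged from 5 to 1254 in astrocytes, 6 to 1321 in oligodendrocytes and 0 to 3888 in neurons, light counts from 0 to 1 in astrocytes, and interaction counts from 0 to 689, 0 to 672 and 0 to 1423. Ttr for time in astrocytes ranged from -0.74 to 4.73. For the interaction in astrocytes Oxt ranged from -5.99 to 3.11, Pmch from -5.76 to 2.86, Hcrt from -4.25 to 4.57 and Gal from -5.63 to 2.48.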

Other observations

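The tests of Ttr and the comparison with Pmch in oligodendrocytes were chosen only after the results were seen. Monoamine genes were higher under light in hypothalamic neurons. At night Slc6a3, the dopamine transporter, had a ratio of 9.08 (6.46 to 13.1), Ddc, which makes dopamine and serotonin, 1.85 (1.66 to 2.06), and Th, the rate-limiting enzyme of dopamine synthesis, 1.79 (1.38 to 2.33), while Hdc, which makes histamine, was at 0.548. By day Th was at 1.75 (1.39 to 2.23) and Slc6a3 at 1.498. A neuron subcluster marked by Slc6a3, Ddc and Th held 55, 21, 93 and 108 nuclei in control day, control night, light day and light night, so the number of these cells differed in the same direction.

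In the hypothalamus 1 other neuron subcluster held 109 nuclei, 106 of them from the light night library. Hypothalamic neurons of that library also had lower Hcrt, which encodes orexin, at 67.4 CPM against 159 in control night, and lower Avp, at 41.5 against 74.2. The subcluster with Hcrt among its markers held 34 nuclei there and 73 in control night.

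The higher level of glucocorticoid-responsive genes at night in control hypothalamic oligodendrocytes may follow the nightly corticosterone peak of mice, which is a hypothesis. RNA from other cells cannot be told apart from it. Of 10 raised members 90% stood at 25% or more of the highest other class, but Pmch, which these cells do not make, met the same criterion at 881 CPM. Less cytoplasmic RNA by day was excluded, as ribosomal protein genes had a night to day median of -0.14 (-0.18 to -0.10). Corticosterone was not measured.

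In the hippocampal light night library the CPM of Ttr differed 5.20 times (4.46 to 6.01) between the highest and lowest of 5 classes, by which uptake of choroid plexus RNA across all classes cannot be told apart from other sources. Per nucleus the means differed 1.254 times (0.976 to 1.60), as a like number of free molecules with each nucleus requires.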
